A study of Homo sapiens with 18 samples.

How the data were processed

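K562 cells, an established human leukaemia line, carried the calcium-permeable channel TRPV1 and the transcriptional repressor dCas9-KRAB per the labels. The series lists 18 samples in a pair of experiments. The first was a pooled CRISPR interference (CRISPRi) screen, in which single-guide RNAs (sgRNAs) direct dCas9-KRAB to promoters and the abundance of each sgRNA in genomic DNA is counted. Cells were collected at day 0 and, with no treatment or with capsaicin, the agonist of TRPV1, at day 14. The second was RNA-seq of polyA RNA from cells pretreated for 3 days with vehicle or piericidin A, an inhibitor of mitochondrial complex I, and then treated for 4 h with vehicle or capsaicin, with 3 libraries in each of 4 groups.

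For the screen, the deposited tables hold counts: whole numbers of reads per sgRNA with no normalization, as the values themselves showed, and sgRNAs without a read are not listed and were taken as 0. MAGeCK is named in the submitters' processing notes, without its role or version. Of the 6 screen samples in the labels, 5 had an analysable counts table, namely both day 0, both untreated and 1 capsaicin library. The capsaicin table is tied to replicate 1 by its name alone, and the other capsaicin sample was not analysed here. For the RNA-seq, the authors deposited FPKM (fragments per kilobase of gene, scaled to library size), with 1 column per library and gene lengths beside them. HISAT2 is named for mapping in the labels' extract protocol, and GRCh38 in the submitters' processing notes; the counting tool and the annotation release are not stated. FPKM multiplied by gene length fell on whole multiples of a single step in each library, within 0.1 of a read, which allowed the reads per gene to be recovered; they were used for depth and for an alternative test.

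FPKM were used as deposited, as log2(FPKM + 1). The 14075 genes with a mean of at least 0.5 FPKM over the 12 libraries were tested with limma 3.58.1 in R 4.3.3, as a linear model of the 4 group means with moderated variances and a mean-variance trend. The 5 contrasts were drawn from that fit, each two-sided: capsaicin after vehicle, piericidin A alone, capsaicin after piericidin A, pretreatment within capsaicin-treated cells, and the interaction, which is the capsaicin effect after piericidin A minus that after vehicle. P-values were adjusted by the Benjamini-Hochberg (BH) method over all tested genes, and an adjusted p under 0.05 is called. Gene lists were tested against the other genes with camera of limma, with a preset inter-gene correlation of 0.01, for lists with at least 5 measured members, and BH adjustment ran over the lists within a contrast; the same test with an estimated correlation was an alternative. Gene names and coordinates came from a name table in which 58207 of the 58735 FPKM gene IDs were found.

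For the screen, 104851 of 105317 sgRNAs had a mean of at least 50 counts over the day 0 libraries and were fitted with the quasi-likelihood model of edgeR 4.0.16, with the total of the non-targeting sgRNAs as library size and a prior count of 2. A score was formed for each transcription start site (TSS) unit with at least 3 sgRNAs, as the mean log2 fold change of its sgRNAs minus the median of the 1890 non-targeting sgRNAs. Its two-sided p came from 1000000 random sets of as many non-targeting sgRNAs, so that 1e-06 was the smallest p possible, with BH adjustment over 20528 units for 18905 genes. A list's median score was compared with 100000 random gene sets of the same size, drawn with replacement, in a two-sided permutation test, whose smallest possible p was 2e-05, with BH adjustment over 33 lists per comparison. Spread in the screen fit came from the day 0 and untreated pairs, and the single capsaicin library was assumed to vary as they did. Numbers were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

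The comparisons, tests, filters, 53 gene lists, of which 33 were meant for the screen and 41 for the RNA-seq, and the rule for naming genes were chosen before the data were examined. The rule took, for each RNA-seq contrast, the genes with the largest increases and decreases among called genes whose group ranges did not overlap and whose higher group had a mean of at least 5 FPKM (10 each way for the main contrasts, 5 for the others). For the screen it took 15 units each way, and in both experiments up to 4 called members of each list, with TRPV1 always included. A selection of these is named in the results. For each list, counts of members called over all genes are given with counts adjusted over the list alone, for which BH adjustment covered the list's members only.

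Alternatives were another pseudocount, weaker and stricter expression or count filters, quantile normalization, median centring, a replicate block, limma without the trend, camera with estimated correlations, leaving out each library in turn, TMM or DESeq2 1.42.0 for the screen, another score or null distribution for the screen units, and sgRNAs pooled by gene. Chosen after the data were seen were edgeR on the recovered reads, a capsaicin score corrected for growth, and a null distribution taken per direction. Spiked fold changes were tested on simulated data with the same libraries' depth and spread. Among 50 changed genes per fold, limma recovered 42% at a fold of 1.2, 76% at 1.5 and 98% at 2 for capsaicin after vehicle, and 20%, 62% and 90% for the interaction, with 8 and 7 false calls. In the screen, all 50 of 50 units changed by a fold of 1.5 or more were recovered in both comparisons, with 26 and 13 false calls.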

Results

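TRPV1-expressing K562 cells were examined in a CRISPRi screen for genes that alter growth or survival under capsaicin, and by RNA-seq for the early response to capsaicin with and without an earlier block of complex I. Per the series description, the screen library targeted 18905 genes with 5 sgRNAs per gene. The screen comprised 2 libraries at day 0, 2 from untreated cells at day 14 and 1 analysed library from capsaicin-treated cells at day 14. Total counts were 73249403 and 56834816 at day 0, 46970120 and 53681035 in untreated cells and 62716525 under capsaicin. The median was 435 to 672 counts per sgRNA. The RNA-seq comprised 4 groups of 3 libraries. Reads recovered from the FPKM were 18647018, 15777873 and 16772182 after vehicle alone, and 18235692, 19085866 and 17731847 after vehicle then capsaicin. They were 20505872, 21423478 and 15129970 after piericidin A then vehicle, and 17617629, 15163879 and 18874358 after piericidin A then capsaicin. The labels do not say that RNA replicates came from separate cultures, so the spread between them, and the p-values built on it, may cover technical variation only. FPKM are given as mean ± SD (n = 3 libraries), and changes as log2 fold changes of FPKM + 1.

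The first RNA-seq comparison asked how cells responded to 4 h of capsaicin after vehicle pretreatment. Capsaicin raised most immediate early genes, the rapid transcriptional response to calcium and growth signals. FOS (ENSG00000170345, GRCh38 chromosome 14, 75278774 to 75282230), a subunit of the AP-1 transcription factor, rose from 0.562 ± 0.0928 to 183 ± 3.82 FPKM (log2 fold change 6.88, SE 0.06, adjusted p = 5.88e-14). FOSB (ENSG00000125740, chromosome 19, 45467995 to 45475179), a second AP-1 subunit, rose from 0.264 ± 0.0293 to 61.0 ± 1.85 FPKM (5.62, SE 0.05, adjusted p = 5.88e-14). DUSP1, a phosphatase of MAP kinases, rose from 4.30 ± 0.541 to 81.8 ± 4.08 FPKM, and KLF6, a zinc finger transcription factor, from 3.88 ± 0.144 to 29.1 ± 1.67 FPKM. TRPV1 itself rose from 14.4 ± 1.07 to 25.2 ± 0.703 FPKM (0.77, adjusted p = 4.52e-06). Here and in the other contrasts, FPKM per gene cannot separate the TRPV1 that these cells carried from the cells' own TRPV1 gene.

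Of 26 measured immediate early genes, 23 rose and 1 fell (25 and 1 adjusted over the list alone), with a median log2 fold change of 1.22, and camera called the list (adjusted p = 2.2e-32, and adjusted p = 0.0143 with an estimated correlation). JUN rose by 2.39, EGR1 by 2.23 and IER3 by 2.22 on the log2 scale. Outside the list, the largest increases included TSC22D3, a glucocorticoid-induced leucine zipper protein, at 2.81. Targets of CREB, a factor activated by calcium and cyclic AMP, had 5 of 9 members raised and 1 lowered (5 and 1 adjusted over the list alone), among them NR4A2 at 1.49 and PER1 at 0.72, with VGF lowered at -0.83 (adjusted p = 0.000134, and adjusted p = 0.126 with an estimated correlation). Of 7 targets of NFAT, the factor controlled by calcineurin, 3 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.00813, and adjusted p = 0.126 with an estimated correlation). NR4A1 rose by 2.07, EGR2 by 1.63 and EGR3 by 1.19, and RCAN1, a calcineurin regulator, changed by -0.26. NR4A1, EGR2 and EGR3 also belong to the immediate early list, as do FOS, DUSP1, NR4A2 and PER1 of the CREB list. In every contrast, calls of the CREB and NFAT lists are therefore not separate from that of the immediate early list. Of 9 NF-kB and cytokine genes, 5 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.00145, and adjusted p = 0.126 with an estimated correlation). NFKBIA, the NF-kB inhibitor, rose from 18.1 to 82.6 FPKM and RELB rose by 1.79.

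ATF4, the main transcription factor of the integrated stress response, rose from 97.8 to 174 FPKM (0.82, adjusted p = 4.75e-09). Of 38 of its targets and other genes of that response, 30 rose and 1 fell (31 and 1 adjusted over the list alone), with a median of 0.28 (adjusted p = 2.51e-17, and adjusted p = 0.0735 with an estimated correlation). PPP1R15A, which directs dephosphorylation of eIF2alpha, rose from 33.8 to 114 FPKM, SLC7A11, the cystine transporter, rose by 0.99 and SLC38A2, an amino acid transporter, by 0.68. Genes of cholesterol synthesis had 10 of 24 members raised and 0 lowered (10 and 3 adjusted over the list alone; camera adjusted p = 0.000462, and adjusted p = 0.358 with an estimated correlation). HMGCS1 rose from 31.6 to 75.4 FPKM. The proapoptotic gene PMAIP1 rose from 2.11 to 8.32 FPKM and the antiapoptotic gene MCL1 rose by 0.51.

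Several lists were called downward, each with a part of its members lowered. Across genes the log2 fold change fell with mean expression (Spearman rho -0.231), and camera compares a list with the other genes. Whether the small medians of these lists exceed that trend was not tested. Of 28 ribosome biogenesis genes 21 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 1.27e-07, and adjusted p = 0.126 with an estimated correlation). POLR1B changed by -0.27 and NCL by -0.22. Of 79 mitochondrial ribosome genes 27 fell and 0 rose (36 and 0 adjusted over the list alone), with a median of -0.11 (adjusted p = 3.38e-07, and adjusted p = 0.126 with an estimated correlation). MRPS26 changed by -0.37 and MRPL16 by -0.28. Of 53 genes of mitochondrial gene expression 18 fell and 1 rose (22 and 2 adjusted over the list alone; adjusted p = 0.000188, and adjusted p = 0.126 with an estimated correlation). PARS2 changed by -0.38 and GFM1 by -0.26. DNA replication genes had 17 of 30 members lowered and 2 raised (20 and 2 adjusted over the list alone; adjusted p = 4.48e-06, and adjusted p = 0.126 with an estimated correlation). FEN1 changed by -0.25 and PCNA by -0.24. Genes of mitosis had 11 of 26 lowered and 1 raised (12 and 1 adjusted over the list alone; adjusted p = 0.000387, and adjusted p = 0.321 with an estimated correlation). CDC20 changed by -0.24. The TCA cycle and pyruvate list had 8 of 24 lowered and 1 raised (9 and 1 adjusted over the list alone; adjusted p = 0.00813, and adjusted p = 0.126 with an estimated correlation). FH changed by -0.26. Its call was also lost with a filter at 5 FPKM (adjusted p = 0.125), with quantile normalization (0.0788) and with edgeR (0.0589).

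Among lists that camera did not call for capsaicin after vehicle, erythroid genes had 2 of 22 members raised and 6 lowered (2 and 8 adjusted over the list alone), with KLF1, the erythroid transcription factor, falling from 104 to 73.3 FPKM and EPOR, the erythropoietin receptor, at -0.48. Targets of p53 had 6 of 16 raised and 2 lowered (6 and 3 adjusted over the list alone), with BTG2 at 1.07 and PLK3 at 1.05. The unfolded protein response had 7 of 24 raised and 3 lowered (7 and 6 adjusted over the list alone), with HERPUD1 at 0.58. Heat shock genes had 3 of 15 raised, among them HSPA1A at 0.64, and 7 lowered, HSPH1 at -0.34 (3 and 7 adjusted over the list alone). Their median was -0.097, their mean 0.006 and the camera direction down. Factors of the integrated stress response itself had 3 of 16 raised and 3 lowered (3 and 4 adjusted over the list alone), with a median of -0.03, a mean of 0.154 and a camera direction up. Complex I subunits had 0 of 37 raised and 1 lowered by limma (0 adjusted over the list alone; camera adjusted p = 0.711), and the 13 mitochondrially encoded genes had 0 members called by limma, with 3 at an unadjusted p under 0.05 (0 adjusted over the list alone). Mitochondrial calcium genes had 5 of 13 lowered and 0 raised, PPIF at -0.13, and antioxidant genes 7 of 23 lowered and 1 raised, KEAP1 at -0.25, with the same counts for both adjusted over the list alone. Of 22 glycolysis genes 3 rose, SLC2A3 at 0.47, and 8 fell (4 and 8 adjusted over the list alone). Of 23 calcium-dependent enzymes 5 rose, CAPN2 at 0.25, and 6 fell, with the same counts adjusted over the list alone. Intrinsic apoptosis genes had 2 of 12 raised and 2 lowered (2 and 3 adjusted over the list alone), with a median of -0.087, a mean of 0.092 and a camera direction down. Of 3 measured fibroblast and epithelial markers, KRT18 rose by 0.28 and KRT8 by 0.21, from 29.9 and 9.56 FPKM (2 raised and 0 lowered adjusted over the list alone). Of 2 measured lymphocyte markers 0 were called by limma, with 0 at an unadjusted p under 0.05.

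In all, limma called 3519 of 14075 genes for capsaicin after vehicle, 1534 higher and 1985 lower, of which 93 rose and 4 fell by more than 1 on the log2 scale. The balance moved with the scaling and the filter, to 1782 higher and 1694 lower under median centring and to 943 and 1855 with a filter at 5 FPKM. The ranges of the groups did not overlap for 40.4% of genes, where chance gives 10%. Fold changes on this scale understate those of weakly expressed genes, since 1 is added to each FPKM.

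**Figure D1:**
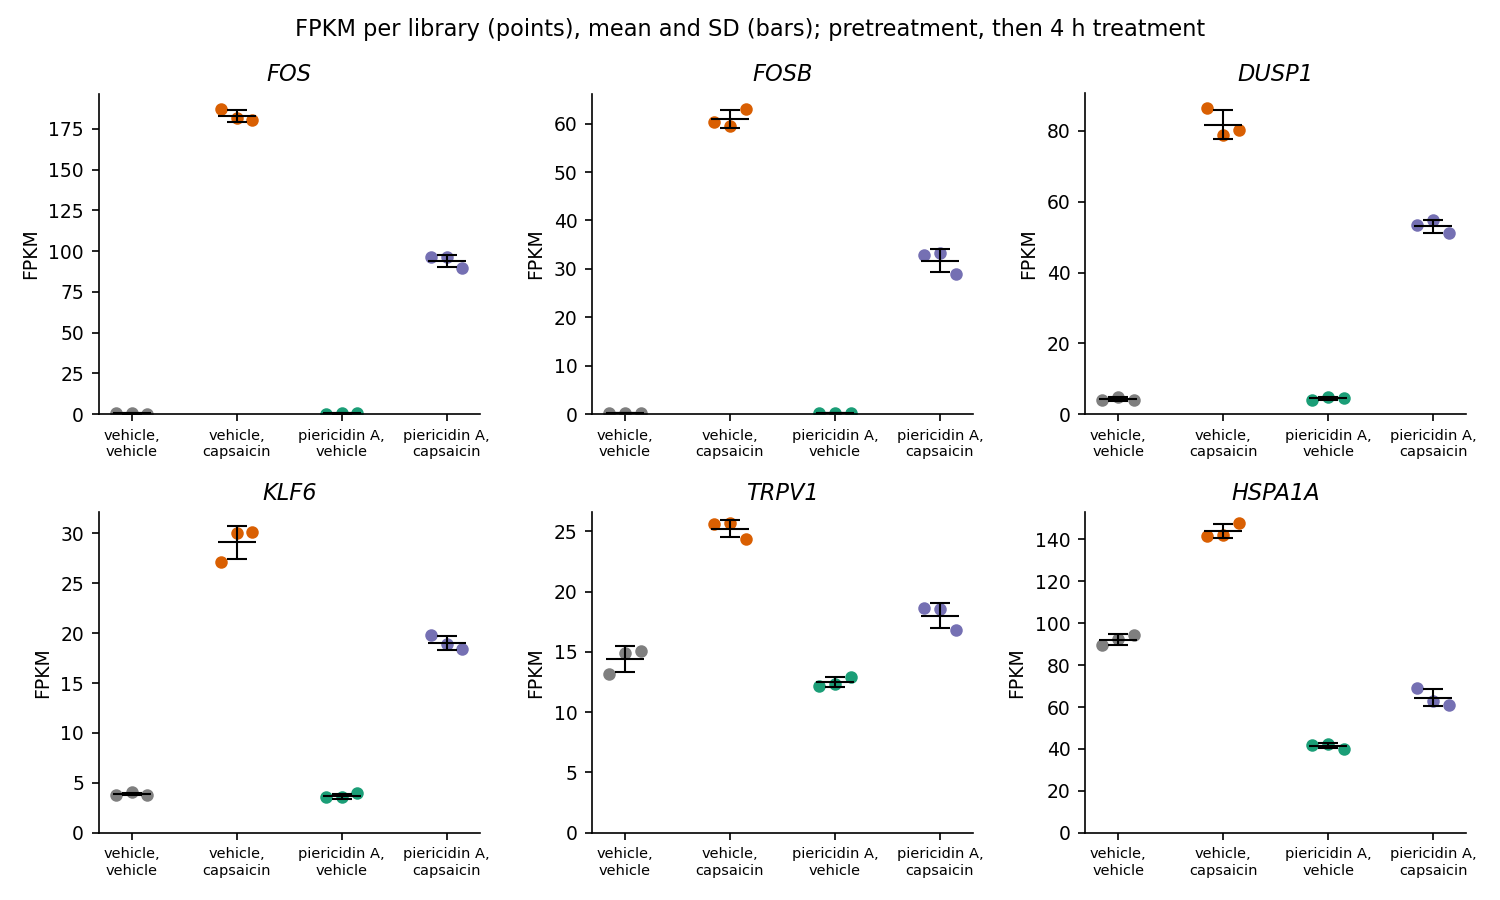
FPKM (y axis) of FOS, FOSB, DUSP1, KLF6, TRPV1 and HSPA1A in the 4 RNA-seq groups (x axis), with points for libraries and bars for the mean ± SD (n = 3). FOS stood at 183 FPKM in capsaicin-treated cells pretreated with vehicle and at 94.1 FPKM in those pretreated with piericidin A.

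The second RNA-seq comparison asked what 3 days of piericidin A did by themselves. Chaperone genes were lower, with HSPA1A, the inducible cytosolic chaperone, falling from 92.2 ± 2.53 to 41.5 ± 1.21 FPKM (-1.13, SE 0.04, adjusted p = 4.31e-07) and HSPA5, the chaperone of the endoplasmic reticulum (ER), from 195 to 135 FPKM (-0.52, adjusted p = 1.43e-05). The nearly identical HSPA1B changed by -0.86, and reads may be shared within that pair. ASS1, an enzyme of arginine synthesis, fell to 6.76 ± 0.904 FPKM (-1.22, adjusted p = 1.43e-05), and PHGDH, the first enzyme of serine synthesis, from 23.0 to 14.8 FPKM (-0.60). CHI3L2, a chitinase-like protein, rose from 19.6 to 32.9 FPKM (0.72), CTH, an enzyme of cysteine synthesis, from 8.64 to 13.0 FPKM (0.53) and SFPQ, a splicing factor, from 155 to 213 FPKM (0.45).

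DNA replication genes had 20 of 30 members raised and 0 lowered (25 and 0 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 2.05e-17, and adjusted p = 0.0192 with an estimated correlation). CDC45 changed by 0.27 and MCM3 by 0.16. The unfolded protein response had 12 of 24 lowered and 0 raised (14 and 0 adjusted over the list alone), with a median of -0.16 (adjusted p = 8.66e-13, and adjusted p = 0.0192 with an estimated correlation). SDF2L1 changed by -0.51 and XBP1 by -0.35. Heat shock genes had 10 of 15 lowered and 0 raised (12 and 2 adjusted over the list alone), with a median of -0.22 (adjusted p = 2.1e-11, and adjusted p = 0.0192 with an estimated correlation), HSPH1 and DNAJB1 both at -0.42. Of the 13 mitochondrially encoded genes 9 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.30 (adjusted p = 6.44e-10, and adjusted p = 0.479 with an estimated correlation). MT-ND1 changed by 0.38 and MT-ND2 by 0.37. That call was lost with quantile normalization (adjusted p = 0.528), under which MT-ND5 changed by 0.0 instead of 0.34. The mitochondrial chromosome took 10.48%, 10.73% and 10.69% of reads after piericidin A against 9.64%, 8.62% and 9.05% after vehicle. Mitochondrial calcium genes had 4 of 13 lowered and 0 raised (5 and 0 adjusted over the list alone; adjusted p = 0.0215, and adjusted p = 0.479 with an estimated correlation). This list lost its call without vehicle replicate 1 (0.0985) or piericidin A replicate 2 (0.0904), with a filter at 5 FPKM (0.142), with quantile normalization (0.111) and with edgeR (0.0544).

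Camera did not call glycolysis genes, of which 5 of 22 rose and 1 fell (9 and 2 adjusted over the list alone; adjusted p = 0.0759), with PKM at 0.30, nor V-ATPase genes, of which 4 of 16 fell and 0 rose (5 and 2 adjusted over the list alone; adjusted p = 0.0839). ATP6V1F changed by -0.29. Of 16 genes of calcium entry and stores 3 fell and 0 rose (3 and 0 adjusted over the list alone), with ATP2A3, a calcium pump of the ER, at -0.52. Of 26 immediate early genes 2 fell, EGR1 at -0.45, and 0 rose (5 and 0 adjusted over the list alone). TRPV1 stood at 12.5 ± 0.40 FPKM after piericidin A (-0.19, adjusted p = 0.0567), which did not pass the test. Of markers of other cell types, 1 of 2 for lymphocytes fell, CD3E at -0.46 from 0.772 FPKM (1 adjusted over the list alone), and 1 of 3 for fibroblasts and epithelia, KRT8 at -0.21 (3 lowered adjusted over the list alone), and 0 of either rose. Both calls were lost without vehicle replicate 1.

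For piericidin A alone limma called 1219 genes, 496 higher and 723 lower, and group ranges did not overlap for 29.7% of genes where chance gives 10%. The count was 596 without vehicle replicate 2, 644 without vehicle replicate 3, 684, 636 and 703 without piericidin A replicates 1, 2 and 3, and 741 with no expression filter.

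The next comparison asked how cells responded to capsaicin after piericidin A. FOS rose from 0.508 ± 0.122 to 94.1 ± 3.75 FPKM (5.98, SE 0.06, adjusted p = 3.39e-13), FOSB from 0.314 ± 0.0352 to 31.7 ± 2.33 FPKM (4.63, adjusted p = 4.63e-13) and DUSP1 from 4.46 ± 0.321 to 53.1 ± 1.83 FPKM (3.31, adjusted p = 2.27e-10). Immediate early genes rose in 23 of 26 cases and 1 fell, with the same counts adjusted over the list alone, and a median of 0.89 (camera adjusted p = 1.53e-46, and adjusted p = 0.00408 with an estimated correlation). TRPV1 rose by 0.49 (adjusted p = 3.29e-04). Of the markers of other cell types, KRT8 rose by 0.29 and KRT18 by 0.28 (2 of 3, and 2 adjusted over the list alone), and 0 of 2 for lymphocytes were called by limma, with 0 at an unadjusted p under 0.05.

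Of 38 ATF4 and stress response targets 19 rose and 0 fell (28 and 2 adjusted over the list alone; adjusted p = 1.44e-19, and adjusted p = 0.0517 with an estimated correlation). PPP1R15A changed by 1.23. Cholesterol synthesis had 7 of 24 raised and 0 lowered, with the same counts adjusted over the list alone (adjusted p = 1.74e-06, and adjusted p = 0.204 with an estimated correlation). HMGCS1 changed by 0.81. NF-kB genes had 5 of 9 raised and 0 lowered (6 and 0 adjusted over the list alone; adjusted p = 1.27e-05, and adjusted p = 0.0876 with an estimated correlation). NFKBIA changed by 1.81. CREB targets had 4 of 9 raised and 1 lowered (adjusted p = 1.44e-05, and adjusted p = 0.0903 with an estimated correlation), and NFAT targets 3 of 7 raised and 1 lowered (adjusted p = 0.00787, and adjusted p = 0.0903 with an estimated correlation), both with the same counts adjusted over the list alone. The unfolded protein response had 7 of 24 raised and 1 lowered (10 and 1 adjusted over the list alone; adjusted p = 0.00611, and adjusted p = 0.26 with an estimated correlation). HERPUD1 changed by 0.37. Targets of p53 had 4 of 16 raised and 0 lowered (5 and 0 adjusted over the list alone; adjusted p = 0.0126, and adjusted p = 0.0903 with an estimated correlation). BTG2 changed by 0.85. Apoptosis inhibitors had 1 of 7 raised, MCL1 at 0.30, and 0 lowered (3 and 0 adjusted over the list alone; adjusted p = 0.0126, and adjusted p = 0.0978 with an estimated correlation); a filter at 5 FPKM ended that call (0.0575).

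The 13 mitochondrially encoded genes, 0 of which were called by limma for capsaicin after vehicle, had 8 members lowered and 0 raised after piericidin A (12 and 0 adjusted over the list alone), with a median of -0.25, MT-ND6 at -0.42 and MT-CO1 at -0.27 (adjusted p = 2.89e-09, and adjusted p = 0.238 with an estimated correlation). Quantile normalization ended this call and turned its direction (adjusted p = 0.924). Mitochondrial ribosome genes had 3 of 79 lowered and 0 raised, with the same counts adjusted over the list alone (adjusted p = 2.34e-05, and adjusted p = 0.238 with an estimated correlation). MRPL16 changed by -0.20. DNA replication genes had 4 of 30 lowered and 0 raised (5 and 0 adjusted over the list alone; adjusted p = 2.34e-05, and adjusted p = 0.145 with an estimated correlation). Ribosome biogenesis had 2 of 28 lowered and 0 raised (4 and 0 adjusted over the list alone; adjusted p = 0.015, and adjusted p = 0.414 with an estimated correlation), a call lost without the first piericidin A library without capsaicin (0.0648), with a filter at 5 FPKM (0.0575) and with edgeR (0.101). Limma called 861 genes, 539 higher and 322 lower, with 26.1% of genes not overlapping between groups where chance gives 10%. The count was 527, 511 and 519 without replicates 1, 2 and 3 of piericidin A then vehicle, and 489 and 550 without replicates 2 and 3 of piericidin A then capsaicin.

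Set side by side, both capsaicin responses raised 462 genes in common (58.7 expected by chance) and lowered 273 (45.4 expected), and their log2 fold changes, which shared no library, had a Pearson r of 0.599 across genes, which are not independent replicates. The slope of the response after piericidin A on that after vehicle was 0.665 by Deming regression over all genes. Resampling genes, not libraries, gave a bootstrap 95% interval of 0.619 to 0.709, which does not cover the spread between libraries. Of the 737 genes called in both with either sign, 81.5% changed less after piericidin A, with a median ratio of 0.753. Choosing genes called after vehicle gave a median ratio of 0.478 and choosing those called after piericidin A gave 0.79, so the ratio moved with the choice of genes.

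The interaction tested whether capsaicin acted differently after piericidin A. FOSB (-0.98, SE 0.07, adjusted p = 5.43e-04), FOS (-0.90, SE 0.08, adjusted p = 0.00217), SOCS3, a feedback inhibitor of cytokine signalling (-0.52, adjusted p = 0.00629), and ATF4 (-0.43, adjusted p = 9.65e-04) responded less after piericidin A. SOCS3 rose from 8.51 to 29.8 FPKM after vehicle and from 7.18 to 17.5 FPKM after piericidin A, and ATF4 from 97.8 to 174 FPKM and from 93.8 to 123 FPKM. DUSP1 (-0.66), KLF6 (-0.52), PPP1R15A (-0.49), HMGCS1 (-0.42), NFKBIA (-0.31) and MCL1 (-0.22) were also called. In the positive direction, HSPH1 (0.27) fell from 48.9 to 38.4 FPKM after vehicle and stood at 36.3 and 34.4 FPKM after piericidin A, and MSH6, a mismatch repair protein (0.25), fell from 22.1 to 17.3 FPKM and stood at 24.4 and 23.0 FPKM. TRPV1 had an interaction of -0.28 that did not pass the test (adjusted p = 0.183).

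Limma called 31 genes for the interaction, 7 positive and 24 negative, with 1819 at an unadjusted p under 0.05. All 31 were called for capsaicin after vehicle and had a smaller absolute change after piericidin A. The sign was the same for 23 of the 24 that rose and 6 of the 7 that fell, and opposite for 1 each, with a median ratio of 0.57 for the 24 that rose and 0.22 for the 7 that fell; the interaction and that contrast share 6 libraries, which favours such a pattern. The number called was 6, 7 and 6 without vehicle replicates 1, 2 and 3, 8, 16 and 4 without vehicle then capsaicin replicates 1, 2 and 3, 8, 9 and 4 without piericidin A then vehicle replicates 1, 2 and 3, and 4, 6 and 4 without piericidin A then capsaicin replicates 1, 2 and 3. FOSB, FOS, SOCS3 and ATF4 passed in each of those 12 fits, and DUSP1, KLF6, PPP1R15A, HMGCS1, NFKBIA, MCL1, HSPH1 and MSH6 did not. The interaction count was 10 with no filter, 47 with a filter at 5 FPKM and 6 with a replicate block. Without the trend it was 7 and with edgeR 106, and a pseudocount of 0.1 ended the call for FOS.

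Camera called 12 lists for the interaction, and 0 with an estimated correlation (8 at an unadjusted p under 0.05). Across genes the interaction rose with mean expression (Spearman rho 0.197), and whether the lists called upward exceed that trend was not tested. Immediate early genes had a median of -0.28, with 5 of 26 members negative and 0 positive (15 and 1 adjusted over the list alone; adjusted p = 2.81e-16, and adjusted p = 0.122 with an estimated correlation). ATF4 and stress response targets had 2 of 38 negative and 0 positive (7 and 1 adjusted over the list alone; adjusted p = 4.05e-08, and adjusted p = 0.194 with an estimated correlation), and CREB targets 2 of 9 and 0 (4 and 1 adjusted over the list alone; adjusted p = 0.000247, and adjusted p = 0.194 with an estimated correlation). Mitochondrially encoded genes had a median of -0.28 with 0 called members by limma, 11 at an unadjusted p under 0.05 (10 negative adjusted over the list alone; adjusted p = 8.96e-11, and adjusted p = 0.225 with an estimated correlation), a call lost with quantile normalization (0.509). Ribosome biogenesis had a median of 0.10 with 0 called members, 14 at an unadjusted p under 0.05 (9 positive adjusted over the list alone; adjusted p = 1.81e-08, and adjusted p = 0.194 with an estimated correlation), and heat shock a median of 0.10 with 1 positive member (7 positive and 2 negative adjusted over the list alone; adjusted p = 0.00397, and adjusted p = 0.225 with an estimated correlation). Mitosis genes (adjusted p = 0.000247, and adjusted p = 0.327 with an estimated correlation) and mitochondrial gene expression (adjusted p = 0.000471, and adjusted p = 0.194 with an estimated correlation) were called upward with 0 called members by limma, 6 and 12 at an unadjusted p under 0.05, and 1 each adjusted over the list alone. Also upward were the mitochondrial ribosome (adjusted p = 0.0023, and adjusted p = 0.405 with an estimated correlation), DNA replication (adjusted p = 0.00635, and adjusted p = 0.346 with an estimated correlation) and the TCA cycle (adjusted p = 0.014, and adjusted p = 0.223 with an estimated correlation). These had 0 called members by limma, 12, 8 and 6 at an unadjusted p under 0.05, and 1, 0 and 0 adjusted over the list alone. Their calls were lost with quantile normalization (0.156, 0.0783 and 0.156) and with a filter at 5 FPKM (0.0837, 0.104 and 0.104), and without piericidin A then vehicle replicate 2 for the mitochondrial ribosome (0.0536) and the TCA cycle (0.0504). NFAT targets were called downward with 0 called members by limma, 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone (adjusted p = 0.0345, and adjusted p = 0.194 with an estimated correlation). They lost the call without vehicle then capsaicin replicates 1 (0.0563) and 2 (0.0607) or piericidin A then capsaicin replicate 2 (0.0549), with a pseudocount of 0.1 (0.205), no filter (0.113), quantile normalization (0.156) and edgeR (0.282).

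**Figure D2:**
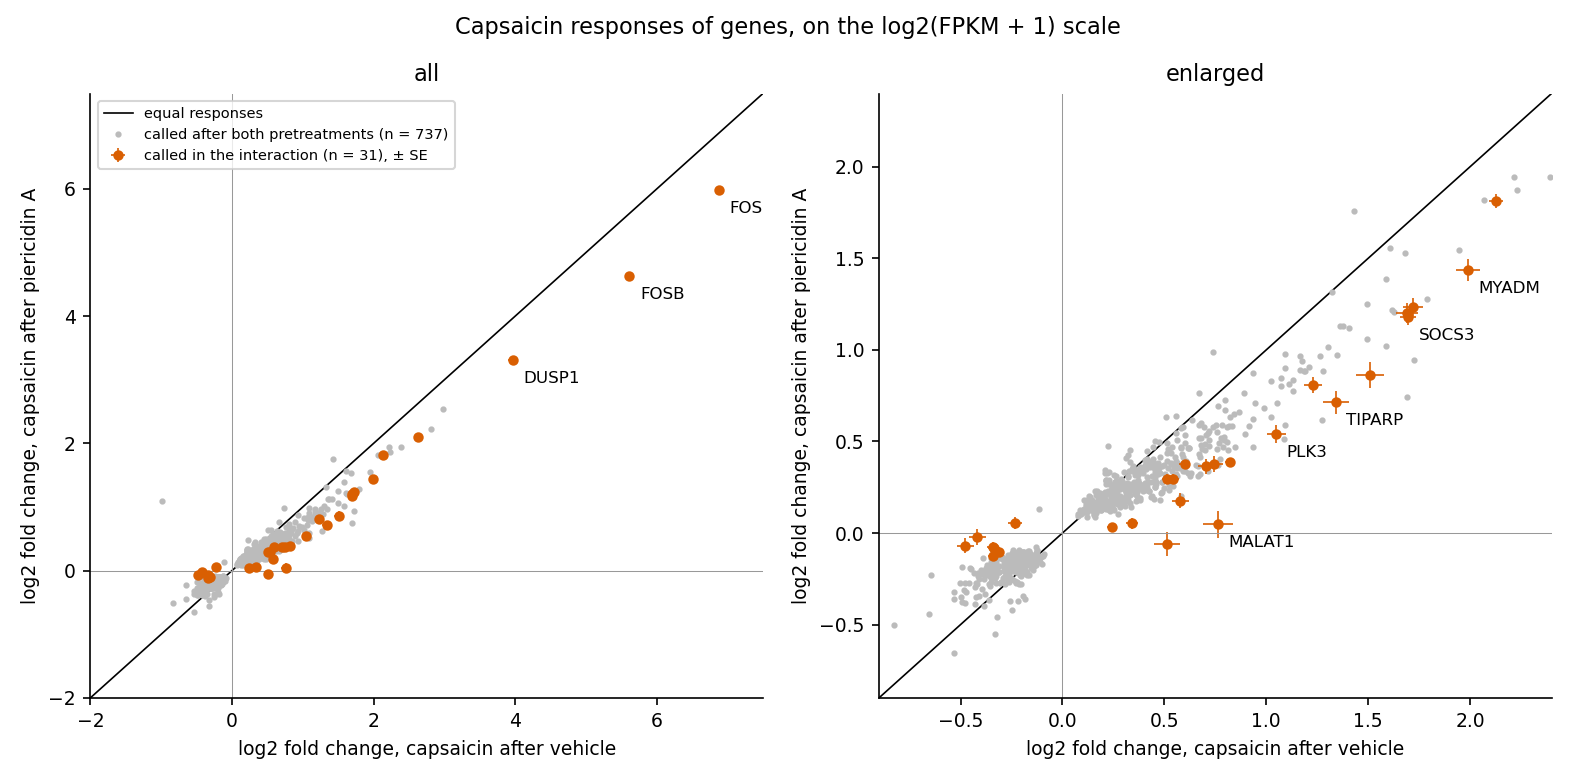
Log2 fold change by capsaicin after vehicle (x axis) and after piericidin A (y axis), with the 737 genes called in both in grey, the 31 genes of the interaction in orange with bars for the SE, and the line of equal response; the right panel enlarges the centre. The 24 interaction genes that capsaicin raised lie below the line and the 7 that it lowered lie above it.

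The last RNA-seq comparison set piericidin A against vehicle pretreatment within capsaicin-treated cells. Its log2 fold change rose with mean expression across genes (Spearman rho 0.133), and whether the higher lists exceed that trend was not tested. HSPA1A stood at 64.4 against 144 FPKM (-1.15, SE 0.04, adjusted p = 3.64e-07), ASS1 at 6.78 against 16.7 FPKM (-1.19), MT2A, a metallothionein, at 2.99 against 8.56 FPKM (-1.26) and HSPA5 at 145 against 219 FPKM (-0.59). The difference was -0.95 for FOS, -0.92 for FOSB, -0.81 for EGR1 and -0.46 for TRPV1 (adjusted p = 4.88e-04). PKM, the last enzyme of glycolysis, was higher by 0.35 and CHI3L2 by 0.65. CD3E, 1 of 2 lymphocyte markers, was called at -0.39 (1 adjusted over the list alone), a call lost without vehicle then capsaicin replicates 1 or 2 or piericidin A then capsaicin replicate 3. Of 3 fibroblast and epithelial markers 0 were called by limma, with 2 at an unadjusted p under 0.05 (1 lower adjusted over the list alone).

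DNA replication genes had 26 of 30 members higher and 0 lower (28 and 0 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 9.6e-19, and adjusted p = 0.0275 with an estimated correlation), and PCNA at 0.29. The unfolded protein response had 12 of 24 lower and 0 higher (14 and 0 adjusted over the list alone; adjusted p = 1.31e-11, and adjusted p = 0.0406 with an estimated correlation). Immediate early genes had 19 of 26 lower and 0 higher (19 and 1 adjusted over the list alone; adjusted p = 1.15e-14, and adjusted p = 0.0575 with an estimated correlation), CREB targets 6 of 9 and 0 (7 and 0 adjusted over the list alone; adjusted p = 1.34e-06, and adjusted p = 0.0721 with an estimated correlation). ATF4 and stress response targets had 15 of 38 lower and 1 higher (16 and 2 adjusted over the list alone; adjusted p = 1.34e-06, and adjusted p = 0.235 with an estimated correlation), and heat shock genes 5 of 15 and 0 (6 and 1 adjusted over the list alone; adjusted p = 0.00586, and adjusted p = 0.235 with an estimated correlation). Higher lists were ribosome biogenesis, with 10 of 28 higher and 1 lower (16 and 1 adjusted over the list alone; adjusted p = 1.46e-05, and adjusted p = 0.199 with an estimated correlation), and mitosis, with 8 of 26 and 1 (13 and 1 adjusted over the list alone; adjusted p = 7.27e-05, and adjusted p = 0.26 with an estimated correlation). Mitochondrial gene expression had 9 of 53 higher and 0 lower, with the same counts adjusted over the list alone (adjusted p = 0.00429, and adjusted p = 0.235 with an estimated correlation), and glycolysis 10 of 22 higher and 2 lower (11 and 2 adjusted over the list alone; adjusted p = 0.00429, and adjusted p = 0.29 with an estimated correlation).

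The remaining lists lost their calls under some choices. Erythroid genes, with 6 of 22 higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.00863, and adjusted p = 0.326 with an estimated correlation), lost the call with a filter at 5 FPKM (0.13). NFAT targets, with 5 of 7 lower and 0 higher (5 and 0 adjusted over the list alone; adjusted p = 0.0147, and adjusted p = 0.148 with an estimated correlation), lost it with a pseudocount of 0.1 (0.0644) and no filter (0.0937). The TCA cycle, with 7 of 24 higher and 0 lower (9 and 2 adjusted over the list alone; adjusted p = 0.0256, and adjusted p = 0.235 with an estimated correlation), lost it without piericidin A then capsaicin replicate 1 (0.062), with a filter at 5 FPKM (0.118), quantile normalization (0.0633) and edgeR (0.0565). NF-kB genes, with 2 of 9 lower and 0 higher (3 and 1 adjusted over the list alone; adjusted p = 0.0258, and adjusted p = 0.272 with an estimated correlation), lost it without that library (0.0685), without vehicle then capsaicin replicate 2 (0.057), with no filter (0.246) and at 5 FPKM (0.209). Cholesterol synthesis, with 8 of 24 lower and 4 higher (8 and 4 adjusted over the list alone; adjusted p = 0.0353, and adjusted p = 0.539 with an estimated correlation), lost it without piericidin A then capsaicin replicate 1 (0.087) or vehicle then capsaicin replicate 1 (0.108). Limma called 2281 genes, 1214 higher and 1067 lower, with 33.1% not overlapping where chance gives 10%, and 1509 without vehicle then capsaicin replicate 3. The balance turned to 978 higher and 1238 lower under median centring, and to 1370 and 1464 with edgeR on recovered reads, an alternative chosen after seeing the data. Piericidin A effects without and with capsaicin shared 260 higher genes (42.8 expected by chance) and 445 lower (54.8 expected).

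In the screen, untreated cells at day 14 were compared with day 0 to show which genes the cells needed for growth. Units whose sgRNAs were lost most were HSD17B10, a mitochondrial dehydrogenase that also serves in tRNA processing (score -6.83 ± 0.78, SD between 5 sgRNAs), the centromere factor MIS18A (-6.51 ± 0.64), the snRNP assembly factor GEMIN5 (-6.46 ± 0.62) and ANAPC4 of the anaphase-promoting complex (-6.40 ± 1.06). Each had an adjusted p of 2.78e-05, given by the smallest p that the non-targeting sets allow. GATA1, the erythroid master regulator, scored -4.92 ± 1.76, and BCR, part of the fusion kinase that drives K562 cells, -2.35. Higher units were SPI1, a myeloid transcription factor (0.84 ± 0.17, adjusted p = 0.0324), and the ubiquitin-conjugating enzyme UBE2L3 (0.76 ± 0.16, adjusted p = 0.0329), and both lost the call when the 3 sgRNAs with the largest effects were averaged. TRPV1 scored 0.01 ± 0.40 (adjusted p = 0.97).

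Essential machinery was depleted: 47 of 48 cytosolic ribosome genes were lower (47 adjusted over the list alone, median -2.86), 24 of 28 spliceosome genes (25, median -3.09), 35 of 38 of RNA polymerase II and Mediator (37, median -1.94, and 1 higher) and 28 of 31 of the proteasome (30, median -1.93). Mitochondrial genes followed, with 72 of 79 of the mitochondrial ribosome lower (77 adjusted over the list alone, median -2.01), 37 of 53 of mitochondrial gene expression (42, median -1.40), 10 of 18 of ATP synthase (10, median -1.12), 21 of 37 complex I subunits (29, median -0.71) and 15 of 31 of complex IV (23, median -0.58). The V-ATPase had 11 of 16 lower (12 adjusted over the list alone, median -1.23). NDUFA8 of complex I scored -2.69 ± 0.12 (n = 5 sgRNAs), MRPS9 -4.78, ATP5B -3.88 and ATP6V1A -5.16. These 10 lists had an adjusted p of 6.6e-05, from the smallest p that the random sets allow.

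Also lower, with medians between -0.14 and -0.51 and counts over all genes followed by those adjusted over the list alone, were complex I assembly factors (7 and 12 of 18), complex III (6 and 10 of 15), the TCA cycle (6 and 12 of 24), coenzyme Q synthesis (4 and 7 of 13), mTORC1 signalling (10 and 15 of 29, with 5 higher), N-glycosylation (7 and 12 of 34) and ER translocation (10 and 14 of 31). The same held for integrated stress response factors (6 and 7 of 16), KRAB repression (5 and 9 of 15), erythroid transcription factors (4 and 6 of 13) and glycolysis (7 and 10 of 23). The highest adjusted p among these was 0.0221, for the erythroid factors; that of glycolysis, 0.0192, rose to 0.0554 without day 0 replicate 1 and 0.066 without untreated replicate 1. The other 12 lists were not called for growth, among them complex II (2 of 7 lower, 3 adjusted over the list alone, adjusted p = 0.161) and mitochondrial calcium (1 of 13, 3 adjusted over the list alone, adjusted p = 0.0724, and 0.0355 without untreated replicate 2). Altogether 2201 units were called, 2 higher and 2199 lower, against 109 higher and 1471 lower with the null per direction, chosen after seeing the data. The main test compares absolute scores, and non-targeting sgRNAs ranged from -5.37 to 0.73 for growth. Higher units were thus judged against the larger losses among non-targeting sgRNAs, which made higher calls hard to reach. By edgeR, 34 of 1890 non-targeting sgRNAs (1.8%) were called against 11.1% of targeting sgRNAs, and 89 and 106 non-targeting sgRNAs without untreated replicates 1 and 2. With random targeting sgRNAs as the null the count was 737. CRISPRi can also repress a neighbour that shares the targeted promoter, which was not examined.

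The second screen comparison asked which knockdowns changed abundance under capsaicin. Relative to untreated cells, the highest units included PTPLB (HACD2), an enzyme of very long chain fatty acid synthesis (score 3.80 ± 0.09, SD between 5 sgRNAs), EMC2 of the ER membrane complex (3.73 ± 0.17), SEC23B of the coat of ER-derived vesicles (3.54 ± 0.50), VPS29 of retromer (3.53 ± 0.68, 6 sgRNAs), RPN1 of the oligosaccharyltransferase (3.48 ± 0.32, 4 sgRNAs), the adaptor GAB2 (3.04 ± 1.32) and MEN1, or menin (2.94 ± 0.26). The lowest included the membrane scaffold genes FLOT1 (-5.46 ± 1.34) and FLOT2 (-3.73), UPF2 (-4.01) of nonsense-mediated decay, and the ER chaperone ERP44 (-3.65 ± 0.86). Each had an adjusted p of 5.93e-05, the lowest attained. TRPV1 scored -0.09 ± 0.50 (adjusted p = 0.837). Whether its sgRNAs lowered the TRPV1 that these cells carried was not measured. This score therefore cannot tell whether the channel mattered under capsaicin.

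Knockdowns of many mitochondrial genes were more abundant under capsaicin. Complex I subunits had 22 of 37 units higher and 1 lower (29 and 1 adjusted over the list alone), with a median of 0.97, NDUFA8 at 2.63 ± 0.19 (n = 5 sgRNAs) and NDUFA9 at 2.39. Its assembly factors had 11 of 18 higher and 0 lower (12 and 1 adjusted over the list alone, median 0.83). The score of TMEM126B was 1.79. Complex III had 9 of 15 higher and 0 lower (11 and 0 adjusted over the list alone, median 0.79), UQCRB at 2.21, and complex IV 19 of 31 and 0 (23 and 0 adjusted over the list alone, median 0.83). The score of COX6C was 1.90. The mitochondrial ribosome had 60 of 79 higher and 0 lower (74 and 0 adjusted over the list alone, median 0.92), MRPS12 at 1.57, and mitochondrial gene expression 25 of 53 higher and 1 lower (37 and 2 adjusted over the list alone). The score of FASTKD5 was 1.39. The TCA cycle had 10 of 24 higher and 0 lower (14 and 0 adjusted over the list alone, median 0.51), PDHA1 at 1.70, coenzyme Q synthesis 4 of 13 and 0 (7 and 0 adjusted over the list alone, median 0.57), COQ2 at 1.64, and ATP synthase 5 of 18 and 0 (9 and 0 adjusted over the list alone, median 0.40). The score of ATP5C1 was 1.10. Each of these 9 lists had an adjusted p of 4.4e-05, from the smallest p possible. Complex II had 0 of 7 units called in the resampling test, 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Its median was 0.20 and the list was not called (adjusted p = 0.0579). Mitochondrial calcium genes were called at a median of 0.14 with 0 of 13 members called in the resampling test, 4 at an unadjusted p under 0.05 (0 adjusted over the list alone; adjusted p = 0.048). That call was lost without untreated replicate 1 (0.0832) or 2 (0.419), with sgRNAs pooled by gene (0.301) and with the growth correction (0.0518).

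Outside mitochondria, ER translocation and membrane insertion had 27 of 31 units higher and 0 lower (29 and 0 adjusted over the list alone, median 1.35). The score of EMC4 was 2.65 and that of SEC61B 2.56. N-glycosylation had 19 of 34 higher and 2 lower (22 and 4 adjusted over the list alone, median 0.75), with DDOST at 2.80, and the proteasome 18 of 31 and 0 (23 and 0 adjusted over the list alone, median 0.68). The score of PSMC1 was 1.39. RNA polymerase II and Mediator had 9 of 38 higher and 2 lower (12 and 4 adjusted over the list alone, median 0.19), with MED23 at 2.25; these 4 lists had an adjusted p of 4.4e-05. KRAB repression, on which the silencing of every target depends, had 4 of 15 higher and 0 lower (6 and 1 adjusted over the list alone; adjusted p = 0.000272). The score of SETDB1 was 2.04. BCR-ABL signalling had 5 of 19 higher and 1 lower (7 and 2 adjusted over the list alone), with SOS1 at 2.51. The test of that list gave an adjusted p of 0.000477, but 0.0826 without untreated replicate 1. CBL, a negative regulator that belongs to the growth suppressor list, scored -1.71. Erythroid transcription factors had 2 of 13 higher and 1 lower, with the same counts adjusted over the list alone (adjusted p = 0.000834, but 0.0661 with a filter at 200 counts). MYB scored 1.39, and GFI1B, the lower member, scored -1.18 (adjusted p = 0.000982, but 0.0685 without untreated replicate 2).

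Called lower were cytosolic ribosome genes, with 13 of 48 units lower and 0 higher (19 and 0 adjusted over the list alone, median -0.31, adjusted p = 4.4e-05), RPL34 at -1.17, and growth suppressors, with 8 of 25 and 0 (12 and 1 adjusted over the list alone, median -0.28, adjusted p = 4.4e-05). The score of TSC1 was -1.19 and that of PTPN2 -1.11. The V-ATPase was also called lower (median -0.28, adjusted p = 0.000206), with 2 of 16 units lower and 0 higher and the same counts adjusted over the list alone. Those 2 units were ATP6V1C1 (adjusted p = 0.0229) and ATP6V1B2 (0.0231), which lost their calls without untreated replicate 1 (0.252 and 0.0713). Among lists not called, mTORC1 signalling had 8 of 29 higher and 5 lower (11 and 9 adjusted over the list alone; adjusted p = 0.391, but 0.0387 without untreated replicate 1), with RPTOR at 2.17 and C12orf66 at -1.72. Glycolysis had 7 of 23 higher and 0 lower (8 and 0 adjusted over the list alone; adjusted p = 0.0547). The score of GPI was 1.91. Calcium entry and pump genes had 1 of 20 higher, TMCO1 at 0.89, and 1 lower, ATP2B1, a plasma membrane calcium pump, at -1.27 (2 and 1 adjusted over the list alone). Intrinsic apoptosis, apoptosis inhibitor, p53 pathway and necroptosis lists had 0 called units in the resampling test over all genes and 0 adjusted over the list alone. At an unadjusted p under 0.05 they had 1, 2, 2 and 0.

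The test called 1433 units, 837 higher and 596 lower, with 3835 at an unadjusted p under 0.05 and 527 called when random targeting sgRNAs formed the null. The single capsaicin library means that this is a comparison between libraries, in which chance events of that culture are not averaged, and 188 of 1890 non-targeting sgRNAs (9.9%) were called by edgeR against 18.4% of targeting sgRNAs. Without untreated replicates 1 and 2, 356 and 334 non-targeting sgRNAs were called. Of the 837 higher units 468 were also lower for growth, as were 296 of the 596 lower units. Independent calls would give 89.7 and 63.8, but the calls were not independent, and no expectation that allows for this was computed. Both scores share the untreated libraries; across units their Pearson r was -0.04 (covariance -0.0116), against -0.262 (covariance -0.0048) for sets of non-targeting sgRNAs with no effect, and -0.028 and -0.015 when different untreated libraries entered each score.

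**Figure D3:**
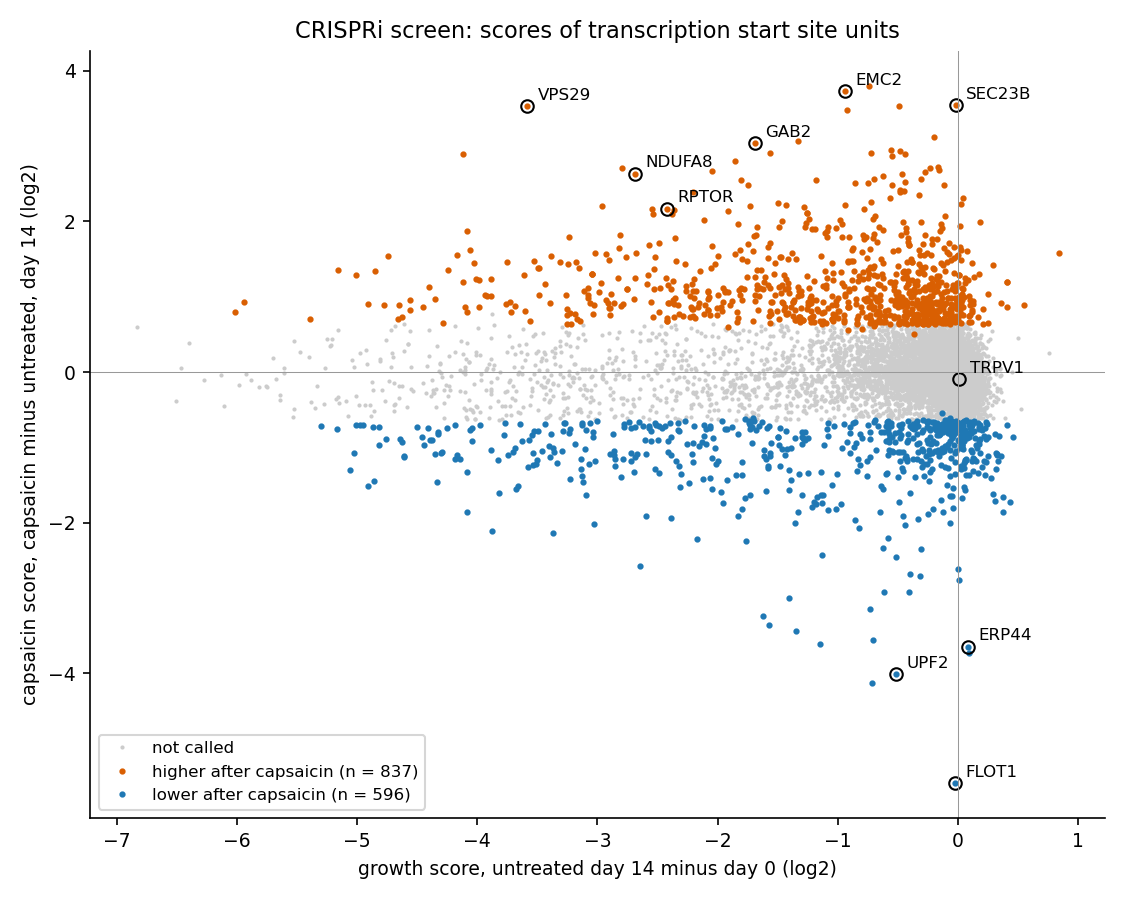
Growth score (x axis, log2, untreated day 14 against day 0) and capsaicin score (y axis, log2, capsaicin against untreated at day 14) per TSS unit, with the 837 units called higher and 596 called lower under capsaicin in colour and selected genes named. EMC2 and SEC23B lie at the top, FLOT1 and UPF2 at the bottom and TRPV1 near the origin.

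**Figure D4:**
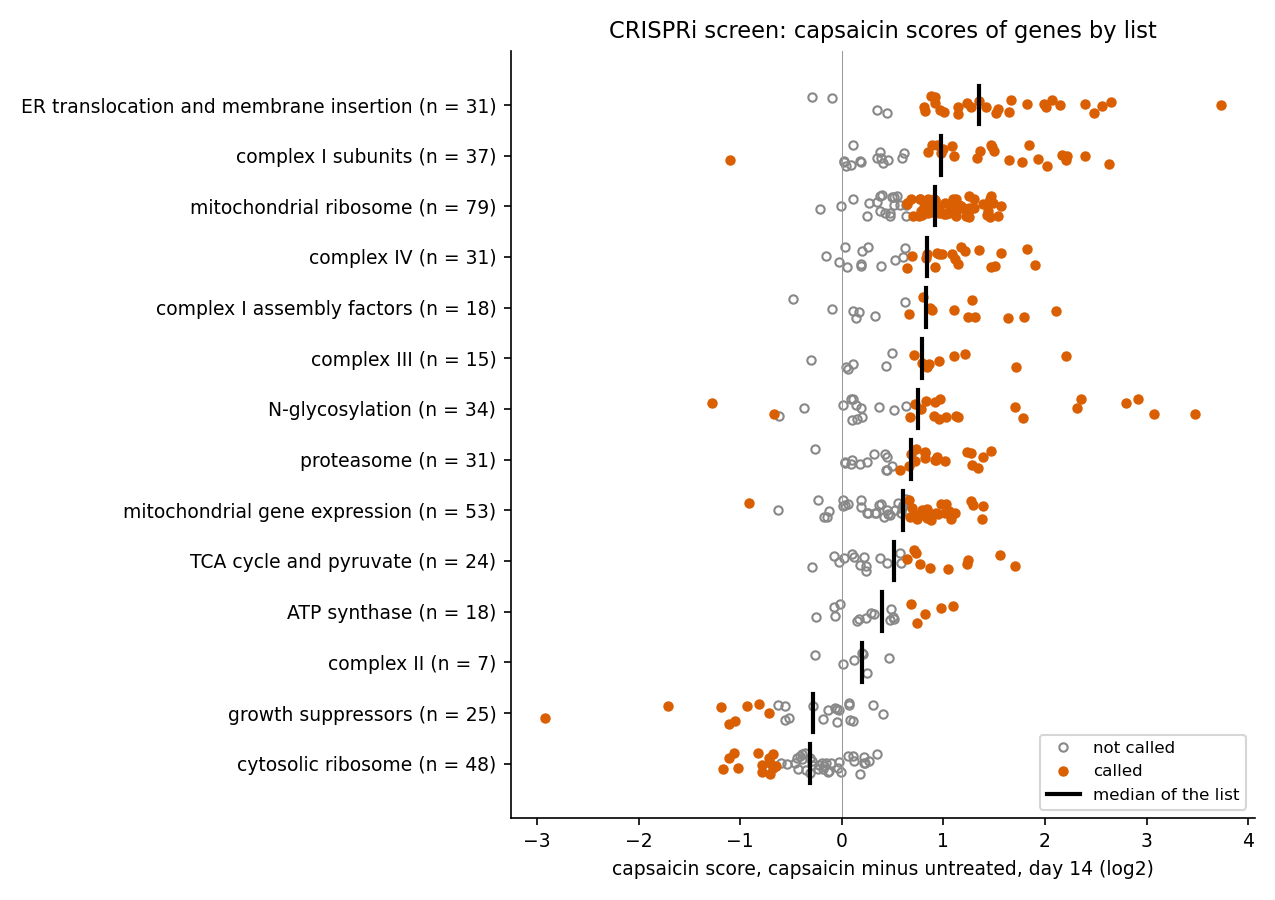
Capsaicin score (log2) of each TSS unit (points, filled where called) for 14 gene lists, with a bar at each list's median. Medians are 1.35 for ER translocation, 0.97 for complex I subunits, 0.92 for the mitochondrial ribosome, 0.20 for complex II and -0.31 for the cytosolic ribosome.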

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

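Of the tests in this part, the scaling, division, drift, count and TRPV1 tests were chosen only after the patterns were seen, while the counts over regrouped libraries were planned.

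Capsaicin acted differently after piericidin A than after vehicle by the test of that difference for 31 genes, and for 12 gene lists, which singled both results out, though 0 of the 12 lists were called by camera with an estimated correlation (8 lists at an unadjusted p under 0.05). With 100 permutations of the residuals, 1 gave as many as 31 genes, the real one, and the highest of the others gave 3, so chance regrouping is an unlikely source of the count. For capsaicin after vehicle, piericidin A alone, capsaicin after piericidin A and pretreatment under capsaicin, 3 against 3 libraries give 10 splits, too few for a share under 0.05. In each, 1 split reached the real count, the real one itself: 3519 genes with 1 for the highest other, 1219 with 0, 861 with 0 and 2281 with 1.

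A first pattern was the smaller capsaicin response after piericidin A. A difference in the scaling of libraries would have lost the calls under other scalings, but median centring and quantile normalization, each taken by itself, kept the calls of at least 28 of the 31 genes, which argues against it. Less TRPV1 transcript after pretreatment is a candidate explanation, since fewer channels could weaken the signal; TRPV1 changed by -0.19 on the log2 scale after piericidin A, short of the threshold (adjusted p = 0.0567), and the data cannot tell whether it contributed. An effect of complex I inhibition on the response itself, or of the altered chaperone and replication transcripts already present before capsaicin, stays open as untested. The interaction count fell to between 4 and 16 when any library was left out, so most of these genes are less certain than FOSB, FOS, SOCS3 and ATF4, which passed each time, although a pseudocount of 0.1 ended the call for FOS.

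The second pattern was the higher abundance under capsaicin of sgRNAs against the mitochondrial ribosome and complexes I, III and IV, lists that were depleted without capsaicin, while complex II was called in neither comparison. Fewer divisions under capsaicin would raise all growth-limiting knockdowns alike, yet the cytosolic ribosome list, more depleted for growth, had a median capsaicin score of -0.312, which argues against this as the whole cause; a part stays open, since the proteasome (median 0.68) and RNA polymerase II and Mediator (0.19) were depleted for growth and called higher. Chance drift of single sgRNAs in the single capsaicin library would leave about as many above as below 0, but 89.7% of 398 mitochondrial ribosome sgRNAs were above 0, the median of the non-targeting sgRNAs, and the electron transport lists tested had 76.9% to 81.5%. Low counts in untreated libraries do not account for all of it, because the 128 mitochondrial ribosome sgRNAs with at least 200 untreated counts had a median of 0.45, against 0.93 for all 398; choosing on untreated counts itself lowers the value. Whether these knockdowns protect cells from capsaicin was not tested apart from a culture-wide difference of the only capsaicin library analysed, and lists outside mitochondria, such as ER translocation (median 1.35), were also higher.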

How the results depend on the processing

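Among the alternatives, edgeR on recovered reads, the growth correction and the null per direction were chosen only after the data were seen; the others were planned. For single genes and units, of 6538 values over the RNA-seq alternatives 5624 kept direction and side of the threshold, 907 lost the call, 5 gained it and 2 reversed; of 2993 screen values 2887 were the same, 105 lost the call, 0 gained it and 1 reversed. The reversed values were MT-ND5 for piericidin A alone (0.0, against 0.34) and MT-ND4 for capsaicin after piericidin A (0.0, against -0.31), both with quantile normalization. MT-ND5 and MT-ND4 both rounded to 0.0 there, so neither shows a change in the other direction. The construction shows the cause for MT-ND4, which ranked 5 in every library, since equal ranks receive equal values. MT-ND5 ranked 13 to 15, so its ranks were close but not equal. Of the 13 mitochondrially encoded genes, 12 ranked within the top 24 in every library. EIF2B3 had a capsaicin score of 0.0 without untreated replicate 2 and -1.24 without untreated replicate 1 (-0.93 with both); the cause was not tested.

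With an estimated inter-gene correlation, 7 of 57 list calls held, namely 1 of 12 for capsaicin after vehicle, 3 of 5 for piericidin A alone, 1 of 13 for capsaicin after piericidin A, 2 of 15 for pretreatment under capsaicin and 0 of 12 for the interaction; lists whose members vary together are then allowed for. With no expression filter, 741 genes and 10 lists were called for piericidin A alone and 10 genes for the interaction. A filter at 5 FPKM gave 47 interaction genes and 7 lists, and quantile normalization 7 lists. The interaction count was 7 without the trend and 106 with edgeR. Random targeting sgRNAs as the null gave 737 growth and 527 capsaicin units. Their log2 fold changes spread wider, with an SD of 0.904 for growth and 0.569 for capsaicin, against 0.259 and 0.356 for non-targeting sgRNAs. Real effects and a wider background were not told apart. For the others the cause was not tested either.

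Leaving out each library in turn gave 596 to 822 genes and 5 to 8 lists for piericidin A alone, 489 to 656 genes for capsaicin after piericidin A, 1509 to 1745 for pretreatment under capsaicin and 4 to 16 for the interaction; the cause was not tested, and fewer libraries leave less power. Called were 2491 to 3212 genes for capsaicin after vehicle, 2162 to 2225 growth units and 1300 to 1584 capsaicin units; of the calls with all libraries, 2386 to 2897, 2105 to 2169 and 1235 to 1366 were kept. Replicate numbers did not pair the RNA-seq libraries: of 18 pairs with the same number 0 had a residual correlation over 0.1 (-0.085 to 0.093). A replicate block gave 3183, 902, 631 and 1895 genes for the 4 contrasts of groups and 6 for the interaction, and 2216 growth and 1374 capsaicin units. The values with edgeR, the growth correction (1417 capsaicin units) and the null per direction (1580 growth units, 109 higher and 1471 lower, and 1435 capsaicin units) were chosen after seeing the data. The growth correction subtracted 0.014 times the growth score. That factor was the median ratio of capsaicin to growth score over 120 essential units (quartiles -0.152 and 0.134). So small a factor left scores nearly unchanged, so the count of 1417 cannot show that growth was allowed for.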

Other observations

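All tests of this part were chosen only after screen or RNA-seq values had been seen.

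Further groups of genes stood out among knockdowns that changed abundance under capsaicin, and their lists were put together after the leading members were seen, so that their p-values are too small. Of 10 genes of nonsense-mediated decay, which removes transcripts with early stop codons, 7 were lower, with UPF2 at -4.01 and SMG5 at -3.44, and SMG8 was higher at 1.69 (median -1.37, permutation test, adjusted p = 5.33e-05, and 8e-05 without the leading genes). Of 7 genes of UFMylation, a ubiquitin-like modification that acts on ribosomes at the ER, 4 were lower, with UFL1 at -3.24 and UFM1 at -1.56 (median -1.28, adjusted p = 5.33e-05, and 0.00016 without the leading genes). The coats of transport vesicles went opposite ways: 7 of 12 genes of COPII, which leaves the ER, were higher, with SEC23B at 3.54 and PREB at 2.67 (adjusted p = 5.33e-05, and 8e-05 without the leading genes). Of 11 genes of COPI, which returns to it, 5 were lower (adjusted p = 9.6e-05, and 0.00036 without the leading genes). COPG1 scored -3.55 ± 2.04 and COPB1 -1.23 ± 1.23 (SD between 5 sgRNAs). The coats also differed in untreated growth, with 7 of 11 COPI genes lower (median -2.69) and 2 of 12 COPII genes (median -0.07).

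Very long chain fatty acid synthesis had 5 of 13 genes higher, with PTPLB at 3.80, ACACA at 2.94 and ELOVL5 at 1.52 (adjusted p = 0.000366, and 0.00658 without the leading genes). Menin and its histone methyltransferase complex had 5 of 8 higher, with MEN1 at 2.94 and DPY30 at 2.11 (adjusted p = 8e-05, and 0.000416 without the leading genes). Prefoldin, a chaperone of actin and tubulin, had 3 of 6 lower, with VBP1 at -3.35 (adjusted p = 0.000107, and 0.00141 without the leading genes). Of 8 retromer genes, VPS29 at 3.53 and VPS35 at 1.81 were higher, and the list was not called (adjusted p = 0.97, and 0.393 without VPS29).

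One hypothesis was that knockdown of complex II changes abundance under capsaicin less than that of complexes I, III and IV. The median capsaicin score was 0.20 for 7 complex II genes and 0.86 for 83 genes of the others, a difference of 0.66 with a two-sided permutation p of 0.0625 (100000 permutations). With 7 genes the test leaves it open whether complex II may differ.

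A further hypothesis was that transcripts lowered by capsaicin overlap the genes whose sgRNAs were higher under it. Among 10509 genes in both data sets, 197 were shared (186.0 expected within deciles of expression, permutation p = 0.343), and 158 without the mitochondrial lists (144.5 expected, permutation p = 0.189), so no excess was shown. Of 8 such overlaps, 1 passed adjustment: raised transcripts shared 63 genes with higher sgRNAs against 92.2 expected (adjusted p = 0.00464). Without the mitochondrial lists this was 59 against 75.5 expected (adjusted p = 0.0674).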
